A study of Homo sapiens with 4 samples.

How the data were processed

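Libraries were made from the RNA of human bone marrow-derived mesenchymal stem cells with an Illumina TruSeq RNA kit, per the labels' protocols. There were 2 control libraries and 2 libraries from cells given 50 µg/mL Laponite nanosilicates for 48 h, and the treatment labels gave each library its group. The submitters' processing notes name CASAVA, STAR and genome build hg19. Versions, read counting and gene models are not given in the sources used here. The authors deposited 1 table of RPKM values (read counts scaled to gene length in kilobases and library total) for 18677 genes with Entrez gene numbers, and no other unit was used as input.

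The deposited RPKM values still held the reads behind them. Each value is a whole number of reads divided by gene length and library total, and solving for these gave whole reads for 100.0% of the 55662 values above 0 (within 1e-06). The library totals were 12871712, 14374440, 11460901 and 8290423 reads for control 1, control 2, nanosilicate 1 and nanosilicate 2. Of the recovered gene lengths 85.0% were multiples of 3 and their median ratio to annotated coding length was 1.000, with 73.0% within 5% of it, so lengths and reads were taken to refer mainly to coding sequence. The unit of length was chosen to lie closest to annotated coding lengths, and multiples were accepted from 0.6 of these. The median ratio is therefore no independent check, and the shares depend in part on these choices. Some genes had recovered lengths far beyond 1 coding sequence, such as HSPA1A (9630 bp) and NEU1 (9984 bp). The reads recovered over all genes came to 100.9% to 101.1% of the totals. One read on a coding length of 1 kb is worth 0.078, 0.070, 0.087 and 0.121 RPKM in these libraries. These figures cover counting error only. The 10 most abundant genes took 30.6%, 29.5%, 26.9% and 27.5% of reads. FN1 alone took 11.2% and 10.4% in control against 7.0% and 7.2% in nanosilicate libraries, and COL1A1 took 8.1% and 7.9% against 9.5% and 9.6%.

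RPKM values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, using an intensity trend in the variance, over the 11045 genes with a mean of at least 1 RPKM over the 4 libraries. The model had 2 residual degrees of freedom per gene and 5.53 prior degrees of freedom. Tests were two-sided, nanosilicate minus control, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes, and ratios are of mean RPKM. Chi-square statistics per degree of freedom for the recovered reads were 2.62 between the controls and 3.31 between the nanosilicate libraries, above the sampling noise, so no pair was treated as 1 library deposited more than once. Repeat libraries of 1 culture could also differ by this much.

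Before the data were examined, 34 gene lists with 760 entries were written for lineage markers, matrix, uptake routes, signalling, stress, metabolism, ribosome and other cell types, along with the design and most alternative settings. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists. Members were counted with adjustment over all genes and over the list alone. With an estimated correlation 0 lists were called by camera. The estimate was 0.00 for oxidative stress, -0.04 for unfolded protein response, -0.03 for immediate early genes and -0.02 for proteases, not above the preset 0.01. A higher correlation therefore does not account for the loss of those calls. With an estimated correlation camera refers its statistic to the 2 residual degrees of freedom. With a preset one the degrees of freedom come from the number of genes. On 2 degrees of freedom and over 34 lists the test has little power, so its missing calls decide nothing about a list. In the other called lists the estimate ranged from 0.02 (YAP response) to 0.89 (ribosomal proteins). At an estimated correlation the unadjusted p was under 0.05 for 1 list, that of the oxidative stress response (0.0465), and fry called 9. Genes are named by a rule written at the same time: the 12 largest rises and 12 largest falls among called genes whose libraries separate by group, up to 3 called members with the smallest p in each list, and a fixed set of lineage and surface marker genes. The rule leaves out short non-coding RNAs, unnamed loci, mitochondrially encoded genes and genes of the sex chromosomes that could identify a donor. Some genes that the rule selects are not reported here.

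Alternatives covered the pseudocount, the filter, scaling between libraries, the variance model, leaving out each library, the replicate number as a block, the set test and a required 2-fold change. Chosen after the data were seen were limma-voom on the recovered reads, thinning of reads to the depth of the shallowest library, and removal from each library of a spline trend (4 degrees of freedom each) with coding length, 3′ UTR length and transcript GC content, alone and with an estimated inter-gene correlation in camera. These properties came from GENCODE release 29 on GRCh38, matched by Entrez number for 99.8% of tested genes. They were used as gene properties only, and no coordinates were used because that build differs from hg19. Near-identical gene copies (keratins such as KRT14, KRT16 and KRT17, metallothioneins, histones, IFITM and ribosomal protein genes with their pseudogenes) may share reads, so their values are uncertain. Overlapping and antisense genes have the same limit, since use of strand in counting is not given in the sources used here.

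The fit was tested on simulated reads for the same libraries, with about 200 genes changed at a time. It recovered 0.0% of genes changed 1.2-fold, 52.6% at 1.5-fold, 90.9% at 2-fold and 99.0% at 3-fold, and called 0 of 11074 genes in a run with no change. Far more genes were called in the data (2463 higher and 2603 lower), so the adjusted threshold there admits larger p-values. The recovery shares therefore do not carry over to the reported fit, which called COL1A1 at 1.19-fold. In the runs with changed genes, 0, 4, 13 and 10 unchanged genes were called at 1.2-fold, 1.5-fold, 2-fold and 3-fold. A lysosome list raised 1.3-fold was called, with 0 other lists. Simulated reads were drawn for each gene independently, with no correlation between genes and no trend with length or GC. That run therefore cannot show how often camera calls lists falsely in these data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for the remaining steps.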

Results

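Messenger RNA was sequenced from human mesenchymal stem cells (hMSCs), multipotent stromal cells grown from bone marrow, with and without exposure to nanosilicates, disc-shaped particles of the synthetic clay Laponite XLG, a sodium magnesium lithium silicate. There were 4 libraries, 2 from cells kept in normal medium (control) and 2 from cells given 50 µg/mL nanosilicates for 48 h and then normal medium for 5 days. Both groups were cultured for 1 week after the start of treatment. Expression of 18677 genes was given in RPKM, read counts scaled to gene length and library total. The number of reads behind each library, recovered from the RPKM values, was 12871712 and 14374440 for control replicates 1 and 2, and 11460901 and 8290423 for nanosilicate replicates 1 and 2. The median tested gene had 207 reads per library. Replicates within a group correlated more closely (Pearson r across genes on the log2 scale, 0.996 for control and 0.993 for nanosilicate) than libraries of different groups (0.968 to 0.980), where genes are not independent replicates. The labels do not say whether replicates came from separate cultures or donors, so p-values measure the spread between these libraries, which may be technical.

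The comparison of nanosilicate-treated with control hMSCs asked how widely a brief exposure to the particles alters the transcriptome of these cells. Treated cells had more RNA of TXNIP, which encodes an inhibitor of thioredoxin and of glucose uptake, and of the cartilage matrix genes COMP, COL11A1 and ACAN, while the cartilage genes HAPLN1 and SOX9 fell to 0.60 and 0.59 of control. The iron and antioxidant genes FTL and NQO1, the stress transcription factors DDIT3 and ATF4, and the lysosomal protease gene CTSD also rose, by 1.62-fold to 2.37-fold. The chemokine gene CCL2, the integrin genes ITGA2, ITGAV and ITGB3, the growth-factor-induced transcription factor gene EGR1 and the mitotic gene TOP2A fell, to between 0.23 and 0.53 of control. Among bone-related genes, COL1A1 rose 1.19-fold, a call lost without either nanosilicate replicate. ALPL fell to 0.71 of control, a call lost without control replicate 2, and SPP1 and BGLAP did not pass the test.

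Of 11045 genes tested with limma, 2463 were higher and 2603 lower in nanosilicate-treated cells at a Benjamini-Hochberg adjusted p under 0.05, which is 45.9% of them. Most changes were modest: the median absolute log2 fold change of called genes was 0.49, and 71 of the higher and 221 of the lower genes changed at least 2-fold. In all 5066 called genes the 2 treated libraries lay on one side of both controls, and among all tested genes 77.3% were separated in this way, where chance gives 33.3% for a single gene. Genes are not independent of each other, so with only 3 splits of the 4 libraries this excess does not exclude chance. Without control replicate 1 the counts were 1160 higher and 1243 lower, and without control replicate 2 they were 1688 higher and 1575 lower. The fold change fell with the length of the 3′ untranslated region (3′ UTR): after the trend with coding length, 3′ UTR length and GC content was removed from each library, 1587 genes were higher and 1417 lower, and 2165 of the 5066 calls were kept.

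**Figure D1:**
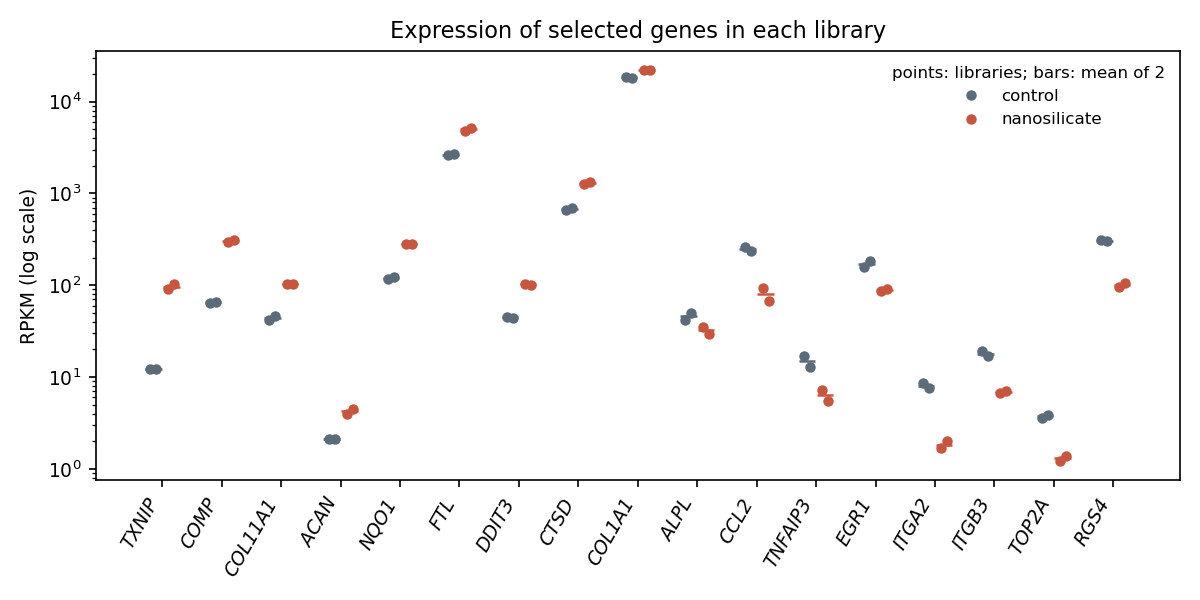
Expression of selected genes, in RPKM on a logarithmic axis, in each of the 2 control and 2 nanosilicate libraries (points) with the mean of each group (bars). TXNIP lies at a mean of 12.2 RPKM in control and 96.5 in treated cells, and CCL2 at 249.1 and 79.9 RPKM, with the libraries of the 2 groups apart for every gene plotted.

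TXNIP (Entrez 10628) had the largest rise, from 12.2 ± 0.155 RPKM in control to 96.5 ± 7.84 RPKM in treated cells (SD, n = 2 each), a log2 fold change of 2.89 with a standard error of 0.09 (limma adjusted p = 9.50e-06). COMP (Entrez 1311), a pentameric glycoprotein of cartilage and tendon matrix, rose from 64.9 ± 2.26 to 305.2 ± 8.08 RPKM (SD, n = 2 each), a log2 fold change of 2.22 with a standard error of 0.06 (limma adjusted p = 9.50e-06). The other 10 of the 12 largest rises had log2 fold changes from 1.94 to 1.47. They were IFITM10, ANGPTL4, an inhibitor of lipoprotein lipase, PLAC9, TMEM190, the keratin gene KRT16, PPP1R14A, an inhibitor of myosin phosphatase, the prostaglandin D synthase gene PTGDS, the tetraspanin gene TSPAN15, CILP2, which encodes a cartilage intermediate layer protein, and EFHD1. TMEM190 was a low gene, at 1.38 RPKM in control and 7.5 RPKM in treated cells, with 10 to 42 reads per library. After removal of the length and GC trend TXNIP was at 3.04 and COMP at 1.93. The other 10 then ranged from 1.98 (IFITM10) to 1.03 (PPP1R14A), and all 12 stayed called.

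The largest fall was that of IL8, the chemokine interleukin 8, with a log2 fold change of -1.91 and a standard error of 0.40 (limma adjusted p = 0.00817). It rested on 0 to 23 reads per library, and the controls averaged 3.79 ± 3.06 RPKM (SD, n = 2). CCL2 (Entrez 6347), which attracts monocytes, was far more abundant and fell from 249.1 ± 19.4 to 79.9 ± 17.4 RPKM (SD, n = 2 each), a log2 fold change of -1.64 with a standard error of 0.14 (limma adjusted p = 5.94e-04). RGS4, a regulator of G protein signalling, fell from 305.1 ± 7.08 to 101.2 ± 7.1 RPKM (log2 fold change -1.58). The other 9 of the 12 largest falls had log2 fold changes from -1.80 to -1.56: CDCP1, the urea transporter gene SLC14A1, ITGA2, the fatty acid desaturase gene SCD, DCBLD2, ATP13A3, HEG1, ITGAV and IL6ST, the shared signalling receptor of the interleukin 6 family. After removal of the length and GC trend these 9 ranged from -1.85 (SLC14A1) to -1.01 (ATP13A3), and all but SLC14A1 were smaller falls. IL8, CCL2 and RGS4 were then at -1.86, -1.86 and -1.33. ITGAV and IL6ST had standard errors of 0.29 and 0.30, since the treated libraries differed from each other (43 ± 22.4 and 7.27 ± 4.19 RPKM, SD, n = 2).

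Genes of the oxidative stress response were called higher as a list by limma's camera test (adjusted p = 3.76e-04 over 34 lists, and adjusted p = 0.713 with an estimated correlation). Of 24 tested members 15 rose and 2 fell, and 15 and 3 did so when adjusted over the list alone. NQO1, a quinone reductase induced by NRF2, rose from 119.6 ± 4.64 to 283.4 ± 0.0641 RPKM (SD, n = 2 each), and FTL, the ferritin light chain, from 2655.4 to 4978.7 RPKM. SOD2, the mitochondrial superoxide dismutase and an NF-kB target, went the other way, with a log2 fold change of -1.42. After removal of the length and GC trend the log2 fold changes of NQO1, FTL and SOD2 were 1.37, 0.55 and -1.23, against 1.24, 0.91 and -1.42 before. The list's median log2 fold change was 0.41, and 0.30 after removal of the length and GC trend.

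The unfolded protein response list was also called higher (camera adjusted p = 0.0161, and adjusted p = 0.713 with an estimated correlation), with 10 of 22 members up and 4 down, the same counts as when adjusted over the list alone. DDIT3, which encodes the transcription factor CHOP, rose from 44.8 to 102.2 RPKM (log2 fold change 1.17), ATF4 from 479.9 to 775.9 RPKM (0.69) and its target TRIB3 from 82.7 to 141.9 RPKM (0.77). HSPA5 rose by 0.47. After removal of the trend DDIT3, ATF4, TRIB3 and HSPA5 were at 0.94, 0.40, 0.38 and 0.76. The 4 members that fell were SEL1L (-0.90), EDEM1 (-0.82), PDIA4 (-0.26) and PDIA6 (-0.23). The median log2 fold change was 0.19, and 0.13 after removal of the trend. Under quantile normalization it was 0.15 and the call was lost (camera adjusted p = 0.317).

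Cytosolic ribosomal protein genes and nuclear-encoded oxidative phosphorylation genes were higher by small amounts in most members. Of 42 ribosomal protein genes 33 rose and 0 fell (36 and 0 adjusted over the list alone), with a median log2 fold change of 0.33 (camera adjusted p = 1.85e-10, and adjusted p = 0.729 with an estimated correlation). RPS19, RPLP2 and RPL24 changed by 0.51, 0.59 and 0.46. Of 30 oxidative phosphorylation genes 23 rose and 1 fell (25 and 2 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 1.45e-05, and adjusted p = 0.729 with an estimated correlation). COX6C and COX4I1, subunits of cytochrome c oxidase, rose by 0.54 and 0.48. CYCS, cytochrome c, had a log2 fold change of -0.49. Both lists hold genes with short 3′ UTRs, of 85 bp and 242 bp in the median, and removal of the trend took their medians to 0.11 and 0.13. It left 18 up and 5 down among ribosomal protein genes and 10 up and 1 down in oxidative phosphorylation. RPLP2 and COX4I1 no longer passed (limma adjusted p = 0.0682 and 0.105). Fry called neither list (adjusted p = 0.0814 for each). Under quantile normalization the ribosomal median was 0.05 and the call was lost (camera adjusted p = 0.0597).

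Inflammatory cytokines and NF-kB targets were called lower (camera adjusted p = 3.76e-04, and adjusted p = 0.713 with an estimated correlation). Of 20 tested members 0 rose and 13 fell, and 16 fell when adjusted over the list alone. Besides CCL2, TNFAIP3, which encodes the NF-kB inhibitor A20, fell from 15 to 6.39 RPKM and the stromal chemokine gene CXCL12 from 138.5 to 96.8 RPKM. The median log2 fold change was -0.47, and -0.45 after removal of the trend. Fry did not call the list (adjusted p = 0.0629).

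Immediate early genes and feedback inhibitors of ERK signalling were called lower (camera adjusted p = 0.0209, and adjusted p = 0.713 with an estimated correlation), with 1 of 25 members up and 11 down, the same adjusted over the list alone. EGR1 fell from 169.7 to 89.8 RPKM, the cyclin D1 gene CCND1 from 186.9 to 109.2 RPKM and PHLDA1 from 29.5 to 15.1 RPKM. SPRED1, SPRED2, SPRY2, SPRY4 and DUSP6 fell too. The member that rose was JUN (log2 fold change 0.21). Among the 13 not called were FOSB, FOSL1, JUNB, EGR2, IER2, IER3, ATF3 and DUSP1. Removal of the length and GC trend changed which members passed. JUNB, IER2, FOSL1 and SPRED3 were then called lower (log2 fold changes -0.34, -0.33, -0.32 and -0.72). JUN, DUSP6, SPRY4 and ETV5 lost their calls (limma adjusted p = 0.0734, 0.299, 0.0966 and 0.234). FOS, at 38.3 and 30.8 RPKM, did not pass (log2 fold change -0.31, limma adjusted p = 0.0766). It was called lower with voom (adjusted p = 0.0159), under quantile normalization (0.0473) and without nanosilicate replicate 2 (0.0087). Genes of the G2 and M phases of the cell cycle were lower too (camera adjusted p = 0.00289, and adjusted p = 0.729 with an estimated correlation). Of 24 tested, 8 fell and 0 rose, also when adjusted over the list alone, among them TOP2A (3.74 to 1.3 RPKM), BIRC5 and CCNA2, all low in both groups. With a filter at a mean of 5 RPKM, which removes low genes of this kind, the list was not called (camera adjusted p = 0.242), nor was it by fry (adjusted p = 0.102). CCNA2 lost its call without either control replicate, at log2 fold changes of -0.61 without replicate 1 and -0.51 without replicate 2 against -0.56 with both. BIRC5 lost its call without control replicate 2, at -0.56 against -0.70. Of 19 S phase genes 1 rose (MCM7) and 1 fell (UHRF1), with 0 passing over the list alone, and the list was not called (camera adjusted p = 0.816). MCM7 and UHRF1 did not pass without control replicate 1 (log2 fold changes 0.32 and -0.69), nor UHRF1 without control replicate 2 (-0.65) or nanosilicate replicate 2 (-0.43). Neither passed after removal of the trend (limma adjusted p = 0.105 and 0.0754). Their log2 fold changes were then 0.26 and -0.52, against 0.45 and -0.67 before. UHRF1 also failed under quantile normalization (0.0719).

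Cholesterol synthesis and uptake genes were called lower (camera adjusted p = 0.0258, and adjusted p = 0.713 with an estimated correlation), with 2 of 21 up and 11 down, or 4 and 13 adjusted over the list alone. INSIG1, a sterol-sensing regulator of the pathway, fell from 28 ± 0.126 to 12.3 ± 2.71 RPKM (SD, n = 2 each) and the synthase gene HMGCS1 from 16.6 to 8.8 RPKM. The median log2 fold change was -0.42, and -0.28 after removal of the trend. Fry did not call the list (adjusted p = 0.0577).

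Of 23 genes for integrins and focal adhesion proteins 2 rose and 12 fell (3 and 12 adjusted over the list alone; camera adjusted p = 0.0119, and adjusted p = 0.713 with an estimated correlation). ITGB1, the common beta subunit, fell from 1109.4 ± 22.2 to 643.3 ± 89.1 RPKM (SD, n = 2 each), ITGA5 from 542.5 to 347.8 RPKM and ITGB3 from 18 to 6.9 RPKM. YAP response genes, which respond to cell tension and spreading, had 2 of 15 up and 10 down, also adjusted over the list alone (camera adjusted p = 0.0258, and adjusted p = 0.713 with an estimated correlation), with TEAD1, AMOTL1 and CRIM1 at log2 fold changes of -1.43, -1.09 and -0.92. The 3 members not called were the abundant gene CYR61 (1277.7 and 1300.6 RPKM, log2 fold change 0.02), ANKRD1 (-0.21) and AMOTL2 (0.11). The stromal surface marker list had 1 of 13 up and 9 down, also adjusted over the list alone (camera adjusted p = 0.0258, and adjusted p = 0.713 with an estimated correlation). Within it NT5E (CD73) fell from 99.6 to 57.1 RPKM and PDGFRA from 14.8 to 5.61 RPKM, while THY1 (CD90) and ENG (CD105) did not pass, at log2 fold changes of 0.10 and 0.11. THY1 was called lower under quantile normalization (-0.12, limma adjusted p = 0.0376). Matrix proteases and their inhibitors had 1 of 14 up and 8 down, or 2 and 9 adjusted over the list alone (camera adjusted p = 0.0362, and adjusted p = 0.713 with an estimated correlation), with ADAMTS1 and ADAMTS12 at log2 fold changes of -0.90 and -1.33 and the inhibitor gene TIMP1 at 0.55. After removal of the trend the YAP, stromal marker and protease lists were no longer called (camera adjusted p = 0.0565, 0.0611 and 0.258). Their median log2 fold changes went from -0.35 to -0.22, from -0.39 to -0.26 and from -0.29 to -0.15. ADAMTS1, ADAMTS12 and TIMP1 were then at -0.56, -0.83 and 0.18. The integrin list stayed called (camera adjusted p = 0.0124, and adjusted p = 0.687 with an estimated correlation), with a median of -0.20 against -0.27. Fry did not call the stromal marker list (adjusted p = 0.0514).

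**Figure D2:**
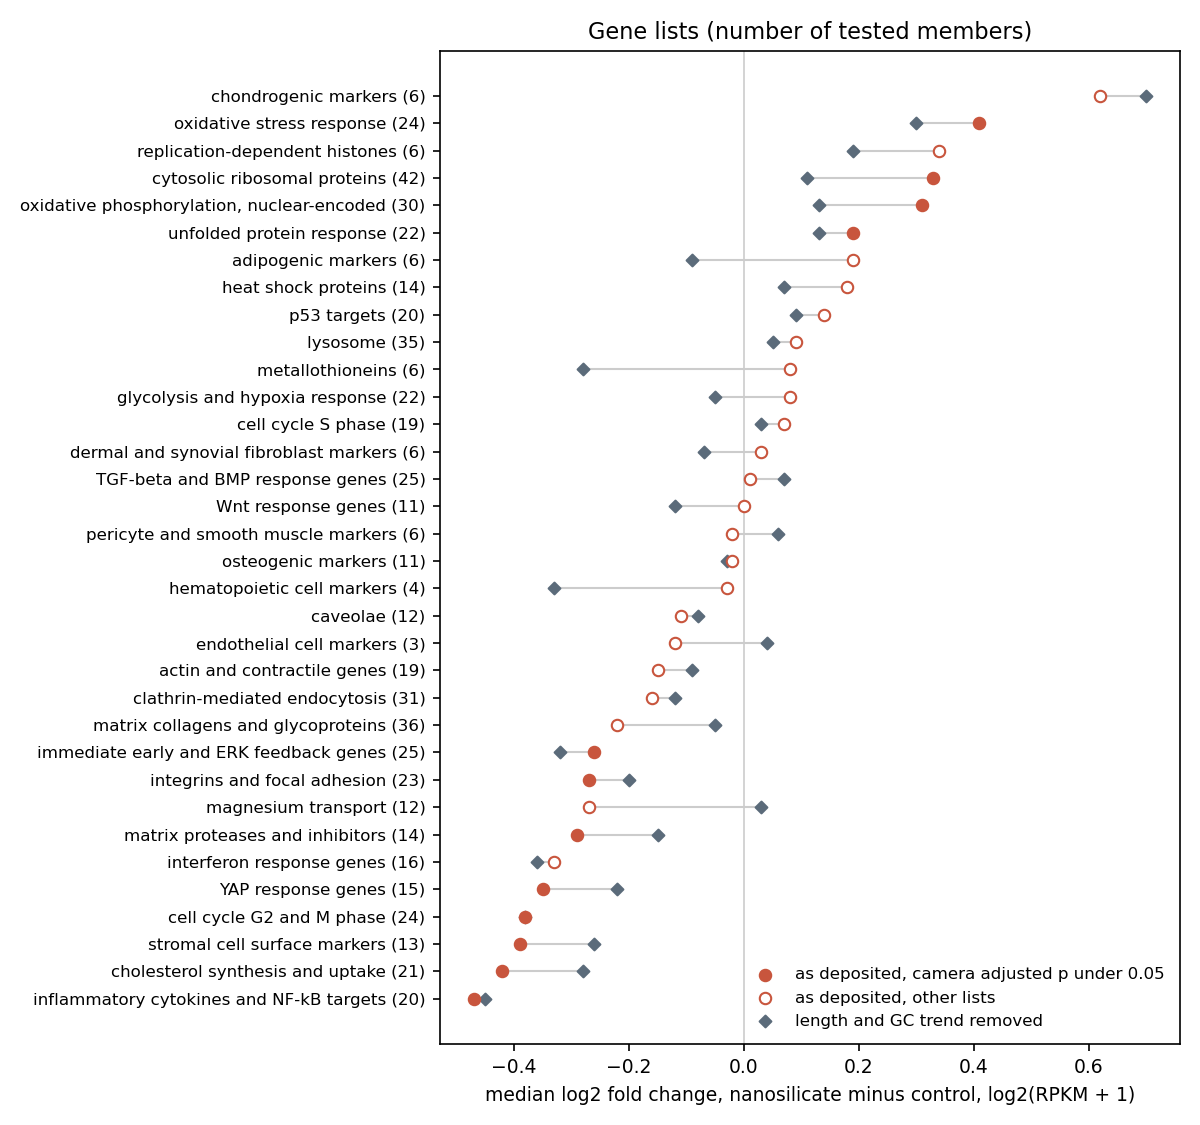
Median log2 fold change of the tested members of each of the 34 gene lists, nanosilicate minus control on the log2(RPKM + 1) scale, from the deposited values (circles, filled where camera gave an adjusted p under 0.05) and after removal of the trend with length and GC content (diamonds). Inflammatory genes lie at -0.47 and -0.45 and ribosomal protein genes at 0.33 and 0.11.

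As among all tested genes (2463 higher and 2603 lower of 11045), lineage markers moved in both directions. Camera called none of their lists, while fry, which does not compare a list with other genes, called the cartilage and fat lists higher (adjusted p = 0.0339 for each) and not the bone list (0.311). The median log2 fold change of the fat list was 0.19, and -0.09 with 2 up and 2 down after removal of the trend. In the cartilage list 3 of 6 tested genes rose and 2 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.222). COL11A1 rose from 44.4 ± 3.4 to 103.6 ± 1.01 RPKM and ACAN, the aggrecan core protein gene, from 2.11 ± 0.0213 to 4.23 ± 0.337 RPKM (SD, n = 2 each). SOX9, the transcription factor that directs cartilage formation, fell from 11.2 to 6.62 RPKM, and the link protein gene HAPLN1 from 238.8 to 143.9 RPKM. The log2 fold changes of COL11A1, ACAN, SOX9 and HAPLN1 were 1.21, 0.75, -0.68 and -0.74. With the trend removed they were 1.56, 0.82, -0.45 and -0.37. COL2A1 was listed at 0 in all 4 libraries. In the bone list 2 of 11 tested genes rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.902). With the trend removed 4 rose and 2 fell. DLX5, a transcription factor of osteoblasts, rose from 3.4 ± 1.52 to 7.84 ± 0.112 RPKM and TNFRSF11B (osteoprotegerin), an inhibitor of osteoclast formation, fell from 164.5 ± 1.3 to 79.3 ± 6.69 RPKM (SD, n = 2 each). COL1A1 changed by 0.25 with a standard error of 0.06 (limma adjusted p = 0.0134), but was at -0.00 under quantile normalization and lost its call without either nanosilicate replicate (adjusted p = 0.164 without replicate 1 and 0.165 without replicate 2), without a filter on low values (0.101) and without the intensity trend in the variance (0.0561). It was at 0.49 after removal of the length and GC trend (adjusted p = 8.51e-04). ALPL, tissue-nonspecific alkaline phosphatase, had a log2 fold change of -0.49 (limma adjusted p = 0.0142, and 0.079 without control replicate 2). BGLAP (osteocalcin, 4.45 and 5.76 RPKM) and SPP1 (osteopontin, 1.61 and 1.17 RPKM) did not pass, on 9 to 22 reads per library for both. BGLAP did under quantile normalization (0.48, limma adjusted p = 0.0486). SP7 had at most 1 read. In the fat list 2 of 6 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.422). CEBPB and CEBPD, early adipogenic factors also induced by stress, changed by 0.71 and 0.89. FABP5 changed by -0.54 but did not pass without control replicate 1 (adjusted p = 0.29) or nanosilicate replicate 2 (0.134). It rested on 5 to 19 reads and also lost its call under thinning (-0.30, adjusted p = 0.388), voom (0.187), quantile normalization (-0.37, adjusted p = 0.168), no filter (0.0857), no intensity trend in the variance (0.0522) and a pseudocount of 0.1 (0.0506). PPARG stayed below the filter at 0.46 and 0.223 RPKM.

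Of 36 matrix collagens and glycoproteins 7 rose and 18 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.0706). It was called lower under quantile normalization (6.05e-05), voom (0.03), a 5 RPKM filter (0.0348), no filter (0.0483), and without control replicate 2 (0.0271) or nanosilicate replicate 2 (0.047). With the trend removed 12 rose and 10 fell, with a median log2 fold change of -0.05 against -0.22 (camera adjusted p = 0.949). The elastic fibre genes ELN and FBLN5 rose from 6.39 to 14.6 and from 73.1 to 127.7 RPKM, and TNC, tenascin C, fell from 100.7 to 53.6 RPKM. For routes of particle uptake, clathrin-mediated endocytosis had 7 of 31 up and 13 down, or 8 and 13 adjusted over the list alone, and was called lower by fry (adjusted p = 0.0339) but not by camera (camera adjusted p = 0.307). The adaptor gene AP2S1 and the light chain gene CLTB rose by 0.61 and 0.86, and SNX18 and the clathrin heavy chain gene CLTC had log2 fold changes of -0.96 and -0.38, that of CLTC being 0.15 after removal of the trend. Caveolae genes were split 3 up and 3 down of 12, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.488), with CAV1 down from 223.1 to 131.7 RPKM. With the trend removed 0 rose and 3 fell (camera adjusted p = 0.297). Among 35 lysosome genes 15 rose and 7 fell, or 15 and 8 adjusted over the list alone (camera adjusted p = 0.193). With the trend removed 6 rose and 5 fell (camera adjusted p = 0.665). CTSD, cathepsin D, rose from 678.1 ± 25.8 to 1310.2 ± 54.5 RPKM (SD, n = 2 each), CTSF from 43.3 to 73.2 RPKM and HEXA from 103.1 to 150.4 RPKM. For handling of magnesium, a constituent of the particle, 1 of 12 transport genes rose and 3 fell, or 0 and 3 adjusted over the list alone (camera adjusted p = 0.375). These were SLC41A1 (-0.51), MAGT1 (-0.87) and TRPM7 (-0.50). They were at -0.26, -0.55 and 0.07 after removal of the trend, and none passed (limma adjusted p = 0.0813, 0.1 and 0.655). SLC41A1 and TRPM7 did not pass without control replicate 1 (adjusted p = 0.0901 and 0.151), TRPM7 under quantile normalization (0.0629) or MAGT1 without a filter (0.0585).

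Signalling lists were split as well. TGF-beta and BMP response genes had 8 of 25 up and 10 down, or 9 and 10 adjusted over the list alone (camera adjusted p = 0.839). ID3, a BMP-induced inhibitor of differentiation factors, rose from 229.1 to 402.0 RPKM, as did ID1, ID2 and ID4 (log2 fold changes 0.90, 0.77 and 0.72, named after their values were seen). The receptor gene TGFBR2 and the latent TGF-beta binding protein gene LTBP1 had log2 fold changes of -1.18 and -0.79. Of 11 Wnt response genes 3 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.594), with WISP1, WNT5A and DKK1 at -1.10, -1.06 and -0.51. Of 20 p53 targets 9 rose and 6 fell, or 9 and 7 adjusted over the list alone (camera adjusted p = 0.375), with BAX and GDF15 up by 0.72 and 0.61 and RRM2B at -0.96. BAX, GDF15 and RRM2B were at 0.47, 0.22 and -0.58 after removal of the trend. Of 16 interferon response genes 2 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.321), with IRF7 at 0.68 (0.27 and not called after removal of the trend) and BST2 and IFITM1 at -0.85 and -1.06. The list was called lower without a filter (camera adjusted p = 0.0252) and without control replicate 2 (0.0306). Of 22 glycolysis and hypoxia genes 8 rose and 4 fell, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.375), among them ANKRD37 (0.78), ENO1 (0.42) and HK2 (-0.94). Of 19 actin and contractile genes 5 rose and 6 fell, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.422), with the tropomyosin genes TPM2 and TPM4 at 0.81 and -0.79, and called lower under quantile normalization (camera adjusted p = 0.0174). Of 14 heat shock proteins 3 rose and 0 fell, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.0945), with CRYAB at 0.91, and called higher with voom (camera adjusted p = 0.0401). Of 6 metallothioneins 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.806): MT2A was at 0.31, and -0.10 after removal of the trend, MT1F at 0.69 and MT1A at -1.47 on 0 to 7 reads. MT1F was at 0.15 and not called after removal of the trend, and MT2A and MT1F did not pass without control replicate 2 (adjusted p = 0.0816 and 0.145) or nanosilicate replicate 1 (0.193 and 0.0888). MT2A also failed under quantile normalization (0.07, adjusted p = 0.494), no filter (0.0906) and no intensity trend in the variance (0.0973), and MT1F with voom (0.118). Of 6 replication-dependent histone genes 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0659), led by HIST1H1C at 0.90. That list was called higher under quantile normalization (camera adjusted p = 0.042) and without control replicate 1 (0.0142) or nanosilicate replicate 1 (0.0254).

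Markers of other cell types were few and showed no common shift. Of 22 hematopoietic markers 4 passed the filter, with 0 up and 1 down (CD68, -0.36, camera adjusted p = 0.816). Of 15 endothelial markers 3 passed it, with 1 up (EGFL7, 0.49) and 0 down (camera adjusted p = 0.91). Of 6 tested pericyte and smooth muscle markers 0 rose and 1 fell (SYNPO2, -0.85; camera adjusted p = 0.806), and of 6 dermal and synovial fibroblast markers 2 rose (S100A4, 0.85, and CD55, 0.43) and 1 fell (DPP4, -0.90; camera adjusted p = 0.839). Counts adjusted over each of these lists alone were the same. CD68, EGFL7 and CD55 did not pass without control replicate 1 (adjusted p = 0.0725, 0.0585 and 0.231), nor did SYNPO2 without control replicate 2 (0.0603) and CD55 without nanosilicate replicate 1 (0.063). EGFL7, with the trend removed, was at 0.04, SYNPO2 at -0.35 and CD55 at 0.34, and none passed (limma adjusted p = 0.821, 0.24 and 0.0738). CD55 also failed without a filter (0.0575) and under thinning (0.0551).

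Genes with long 3′ UTRs were lower and genes with short 3′ UTRs higher in treated cells. With tested genes divided into 5 groups of equal size by 3′ UTR length, from shortest to longest, the median log2 fold change was 0.27, 0.17, -0.01, -0.23 and -0.38. In the shortest group 46.8% of genes were called higher and 8.3% lower, and in the longest group 6.8% and 50.6%. The median 3′ UTR was 359 bp for genes called higher, 2346 bp for genes called lower and 914.5 bp for genes not called. The rank correlation with 3′ UTR length was -0.52 for the fold change, -0.29 for the difference between the 2 nanosilicate libraries and 0.18 for that between the 2 controls, across 11023 genes, which are not independent replicates. The trend-removed counts of the remaining lists, up and down, were as follows. Uptake, matrix and adhesion lists had 4 and 5 (clathrin-mediated endocytosis), 2 and 7 (proteases), 3 and 12 (integrins), 1 and 6 (YAP response), 2 and 7 (stromal markers), 2 and 6 (actin and contractile genes) and 0 and 0 (magnesium transport). Signalling and cell cycle lists had 4 and 7 (TGF-beta and BMP response), 2 and 4 (Wnt), 0 and 12 (immediate early and ERK feedback), 2 and 0 (S phase), 0 and 8 (G2 and M phase) and 9 and 4 (p53). Cartilage genes had 4 and 2, cholesterol 0 and 8, glycolysis and hypoxia 7 and 4, histones 2 and 0, heat shock 3 and 1, interferon response 1 and 5 and metallothioneins 0 and 2. Markers of other cell types had 0 and 1 (hematopoietic), 0 and 0 (endothelial), 0 and 0 (pericyte and smooth muscle) and 1 and 2 (fibroblast). The oxidative stress list had 12 up and 2 down, the inflammatory list 0 and 12 and the unfolded protein response list 10 and 4.

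**Figure D3:**
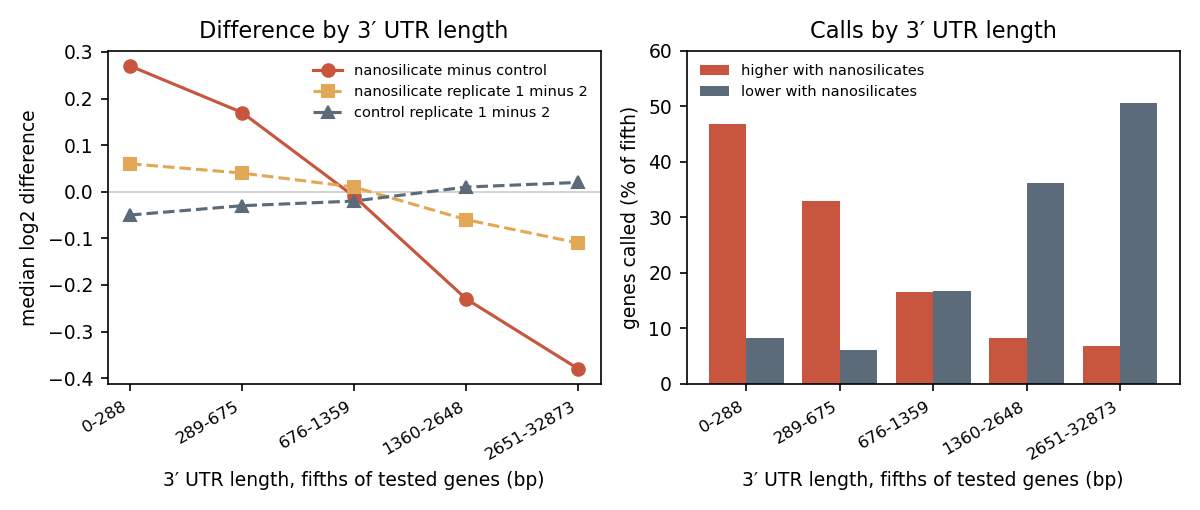
Left, median log2 difference in 5 equal sets of genes by 3′ UTR length (bp), between groups and between the replicates of each group; right, the percentage of genes in each set called higher or lower with nanosilicates. The between-group median goes from 0.27 to -0.38, and the share called lower from 8.3% to 50.6%.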

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

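The groups of 2 are too small for a search for outlying libraries, and no second contrast exists, so the 3 patterns weighed here were chosen from the results. The test of a treatment effect on long 3′ UTRs was chosen only after the result was seen, as were the thinned and trend-removed fits.

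Large numbers of genes were called in both directions, 2463 higher and 2603 lower. A difference in depth as the whole cause is argued against, since 4397 genes were called after all libraries were thinned to the shallowest. A trend with coding length, 3′ UTR length and GC content is argued against as the whole cause too, but only by the calls kept after its removal. These were 2165 of the 5066 (42.7%), and 22 turned direction. The prediction for the trend, set on the total, was not met, at 3004 genes called. Of that total 817 had not been called before, so it does not measure how many calls the trend caused. The 4 libraries allow 3 splits, too few for a share under 0.05; the real split called 5066 genes and the highest of the others 0. Part of the calls therefore stays open between the trend and the treatment. For all calls, a difference between cultures or libraries unrelated to the particles cannot be told apart from the treatment in this design.

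The fold change fell with 3′ UTR length. GC content as the source is argued against by a rank correlation of -0.43 between fold change and 3′ UTR length with GC held constant. A candidate explanation is coverage shifted towards the 3′ end of transcripts in the treated libraries, for example through RNA quality, because reads appear to have been counted mainly over coding sequence and long 3′ UTRs would then draw reads away. It predicts that long coding sequences fall even where 3′ UTRs are short. Among the 3676 genes with a 3′ UTR of at most 519 bp the rank correlation of fold change with coding length was -0.30. Within groups the picture was mixed, over all 11023 genes. The difference between the 2 nanosilicate libraries correlated at -0.29 with 3′ UTR length but at -0.03 with coding length. Between the 2 controls both correlations were 0.18. A treatment effect on genes with long 3′ UTRs cannot be told apart from a coverage shift. The slopes differed between groups by 3.60 times the largest difference within a group, but such a shift would follow the same groups.

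The same trend bears differently on the gene lists. For the oxidative stress list (median log2 fold change 0.30 after removal of the trend, camera adjusted p = 2.55e-04) and the inflammatory list (-0.45, camera adjusted p = 1.80e-04) it is argued against as the whole cause at the preset correlation; with an estimated correlation neither list is called after removal of the trend (adjusted p = 0.687 for each) or before it (adjusted p = 0.713 for each). For ribosomal protein and oxidative phosphorylation genes it cannot be told apart from a change of the lists themselves, since removal took the medians from 0.33 to 0.11 and from 0.31 to 0.13 while both stayed called (camera adjusted p = 0.0119 and 0.0206 at the preset correlation, adjusted p = 0.917 and 0.719 with an estimated correlation). A response of the oxidative stress and inflammatory genes to nanosilicates is therefore a hypothesis, and with 2 libraries per group a difference between cultures unrelated to the particles stays open and untested. Fits with an estimated correlation rest on 2 residual degrees of freedom and have little power, so their missing calls decide nothing.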

How the results depend on the processing

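The voom, thinned and trend-removed fits, and the last with an estimated correlation, were chosen after the data were seen. Counts of higher and lower genes stayed within 1.5 times of 2463 and 2603 under both other pseudocounts, both other filters, both other scalings, both other variance models, voom (2708 and 2965) and thinning (2130 and 2267). Without 1 library they ranged from 1160 to 2745 higher and from 1243 to 2909 lower. The lowest were without control replicate 1, and without control replicate 2 the lower count was 1575; a lone library is then assumed to vary like the other group. With a required 2-fold change, which can only remove calls, they were 71 and 221. After removal of the trend they were 1587 and 1417, with 817 genes called that were not called before; the cause was not tested. The replicate block, a number the labels do not say pairs anything, gave 2519 higher and 2726 lower, and same-numbered libraries did not deviate together (correlation -0.06). Under it FOS and the histone list passed and COL1A1 did not (adjusted p = 0.0144, 0.0347 and 0.111). Lists called by camera numbered 4 higher and 8 lower. With an estimated correlation they were 0 and 0 (also 0 and 0 with the trend removed as well), with fry 4 and 5, and after removal of the trend 5 lower. Leaving out a library gave 4 to 5 higher and 8 to 10 lower. Fry lost 6 of the 12 camera calls and called the cartilage, fat and clathrin lists besides; it tests direction without comparison to other genes. For the oxidative stress, unfolded protein response, immediate early and protease lists the estimated correlation did not exceed the preset one. A higher correlation thus does not account for their lost calls. Camera uses the 2 residual degrees of freedom when the correlation is estimated, which leaves little power over 34 lists. For the oxidative stress list, at an estimate of 0.00, the unadjusted camera p went from 4.42e-05 to 0.0465. Why lists differ between camera and fry was not tested.

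Some named genes turned sign. COL1A1 was -0.00 and THY1 -0.12 (called lower) under quantile normalization, and MT2A -0.10, TRPM7 0.07 and CLTC 0.15 after removal of the trend; the cause was not tested. Of the named genes, 14 more lost their call after removal of the trend, among them HSPB1, COX4I1, RPLP2, MAGT1 and UHRF1. Calls lost without control replicate 1 numbered 11 (such as FABP5, UHRF1, TRPM7 and MCM7), without control replicate 2 numbered 9, and without nanosilicate replicates 1 and 2 numbered 5 and 3. Depth limits genes such as IL8, MT1A, MT1F and SP7, which had at most 23 reads in any library.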

Other observations

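Genes in this paragraph lie outside the naming rule and were chosen after their values were seen. They are single genes, and no group they belong to was tested. Among keratin genes, KRT14 rose from 8.67 to 20.2 RPKM, KRT17 from 12 to 32.1, KRT34 from 8.25 to 19.8 and KRT7 from 52.2 to 101.5 RPKM, while KRT8 and KRT19 did not pass (log2 fold changes 0.10 and -0.02). The filaggrin gene FLG rose from 13.4 to 27.7 RPKM. Rises were also seen for the microfibril gene MFAP5 (338.2 ± 22.4 to 706.2 ± 4.22 RPKM, SD, n = 2 each), THBS3, a relative of COMP (52.9 to 128.2 RPKM), SMOC1 (5.46 to 16.2 RPKM) and the stimulator of chondrogenesis gene SCRG1 (14.5 to 36.4 RPKM). ARRDC4, an arrestin-domain relative of TXNIP, rose from 1.95 to 5.02 RPKM. The chromatin protein genes HMGA1 and HMGA2 fell, with log2 fold changes of -1.10 and -1.32 (limma adjusted p = 2.87e-04 and 0.0016).

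A hypothesis drawn from the rise of ATF4, DDIT3, TRIB3, ASNS and CHAC1 was that other targets of ATF4, which drives amino acid synthesis and transfer RNA charging under stress, rose as a group. The 30 genes used were chosen from known targets after the fold changes had been computed and before the group was tested, leaving out members of the 34 lists. Of these, 16 rose, 2 fell and 12 did not pass, with a median log2 fold change of 0.23 (camera adjusted p = 1.64e-04 over the 34 lists and this one, and adjusted p = 0.651 with an estimated correlation). After removal of the length and GC trend 20 rose and 2 fell, with a median of 0.30 (camera adjusted p = 8.11e-06, and adjusted p = 0.662 with an estimated correlation). The glycyl transfer RNA synthetase gene GARS rose from 307.2 to 504.2 RPKM, PHGDH, which opens serine synthesis, from 146.5 to 216.5, and PCK2 from 76.8 to 129.0 RPKM, while the amino acid transporter gene SLC38A2 fell from 154.2 to 69.8 RPKM. The calls at the preset correlation go with the hypothesis. The fits with an estimated correlation rest on 2 residual degrees of freedom and have little power, so they decide nothing here. ATF4 protein or activity was not measured.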
